A study of Homo sapiens with 48 samples.

How the data were processed

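CUT&RUN libraries of 3 human cell lines (Kasumi-1, HEL and OCI-LY1) were taken as the authors processed and deposited them: 48 libraries in 24 groups of 2, which the submitters describe as biological replicates. Cells carried SMARCA5 fused to an FKBP12 degradation tag and 1 FLAG epitope and were treated with 500 nM dTAG-47. FLAG was profiled untreated and at 18 h, CTCF at 0, 2, 6 and 24 h in each line, ETOZnf and RUNX1 at 0 and 24 h in Kasumi-1, and H2AZ and H3K27me3 in untreated Kasumi-1. Per the labels' protocols, DNA of the FLAG libraries was extracted with phenol and chloroform and that of the CTCF libraries with a column kit, and libraries were made with a NEBNext Ultra II kit. FLAG and CTCF libraries are therefore compared here by position, not by level. Groups and replicate numbers were taken from the sample titles. Some labels of second replicates name dTAG48 in place of dTAG-47, and they were read as the same treatment, as the treatment protocol names dTAG-47.

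Per the submitters' processing notes, the tools were Trimmomatic 0.32, Bowtie2, SAMtools, MACS2, DiffBind, DESeq2, DESeq and deepTools and the genome build hg19 (GRCh37). The notes used here give the tools without order or parameters, and versions of the other tools are not given in the sources used here. The deposited peak lists were called per library by the authors, 46 as narrow and 2 (H3K27me3) as broad peaks. In them the authors' peak caller gives each peak a fold enrichment (a linear ratio over background within that library) and a −log10 q value. These were used to filter peaks or to rank them within a list. The fold enrichment of H3K27me3 sites with and without SMARCA5 was also compared by its median. The lowest −log10 q in the deposited lists was 2.00 among narrow lists and 2.01 among broad lists. It lay between 3.00 and 3.19 in the FLAG lists and between 2.00 and 2.02 in the lists of all other targets. A SMARCA5 peak thus passed a stricter threshold than a CTCF or H2AZ peak.

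The 14 deposited site tables hold, for each site, raw read counts per library as the authors counted them, without normalization. They also hold the authors' mean signal (counts divided by a size factor per library, then averaged), their log2 fold change and their adjusted p-value from DESeq2, per the file headers. The authors' size factors, which the deposited tables' names give as based on total counts, were recovered from the signal and the counts, with a residual of 9.55e-12 or less. At least 99.97% of sites in each table span 400 bp. The count columns are named by group and a letter A or B, and carry no replicate number. The 3 CTCF tables of a line hold the same sites and counts. Another 92 per-sample columns of normalized values were not used. Start and end are given as the deposited tables give them and were read as counted from 1.

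Site tests used edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with its quasi-likelihood test on the raw counts of the 4 libraries compared. Library sizes were set in proportion to the authors' size factors, sites were filtered with a minimum count of 10 (filterByExpr), and a site was called at a Benjamini-Hochberg adjusted p under 0.05. A median change over all sites is part of the result under this scaling and rests on it. The scaling was taken as total-count from the table names, and the sources used here do not tell whether a spike-in entered the authors' size factors. Each test was tested on simulated data, with counts drawn for the real sites and 200 changed sites. At a true log2 change of -2, edgeR recovered 80% of changed sites for FLAG in Kasumi-1, 28% in HEL and 100% in OCI-LY1. For CTCF at 24 h it recovered 84%, 96% and 98%, for ETOZnf 84% and for RUNX1 6%. At a log2 change of -1 it recovered 12%, 2% and 64% for FLAG, 36%, 24% and 64% for CTCF at 24 h, 50% for ETOZnf and 0% for RUNX1. False calls in these 8 comparisons made up 0.0663% of unchanged sites or less. The simulated counts varied independently between sites, and no simulated library shifted as a whole. Real libraries did so: RUNX1 at 24 h stood at 74.4% and 165% of the 0 h mean, and FLAG at 18 h in HEL at 32.1% and 14.3% of the untreated mean. These rates therefore do not carry over to such libraries or to comparisons in which most sites changed.

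Peak sites of a group were places with a peak in both replicate libraries, with an overlap of at least 1 bp. A site was kept in a treated library that had a peak there, lost when neither treated library had one, and kept in both when each had one. Numbers of peaks per library were compared by the mean log2 ratio over lines with an exact two-sided permutation test within lines. With 12 libraries the smallest p is 0.00926, and with 2 libraries against 2 it is 0.333. Overlap of SMARCA5 sites with the other marks was set against 100 circular shifts of the sites along each chromosome. Association of CTCF loss with SMARCA5, H2AZ or H3K27me3 was tested with Fisher's exact test over sites and with Mantel-Haenszel odds ratios within 5 strata of equal size of 0 h peak strength, or of the 0 h scaled count for count tests. Site groups in the count tests were compared the same way, with Benjamini-Hochberg adjustment over 89 tests. Intervals are at 95%, and p-values below 1e-300 are given as that bound. Sites matched between lines were at most 200 bp apart. Sites and regions are not independent replicates, so that intervals and p-values over sites describe these libraries.

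Replicates were compared before they were averaged: no peak lists were identical, and the chi-square per degree of freedom between the count columns of a group ran from 1.16 to 2.57, so that all pairs differed by more than sampling noise and each library was counted once. Scaled counts are counts divided by the authors' size factors, given as mean ± SD over 2 libraries. Total counts over sites per library, from 115525 to 7740568, set the precision, and fragments without molecular identifiers are not independent molecules.

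The rule for named sites, the tests and the alternatives were fixed before the data were examined; exceptions are named where they appear. Among called sites with a mean signal at or above the table's median, the 10 largest falls and the 5 largest rises per comparison were eligible, and a selection of them is named. For CTCF the 24 h comparison decided, and its sites were followed at 2 and 6 h. Alternatives were an adjusted p under 0.01, a fold of at least 2, TMM scaling, DESeq2 1.42.0 with its own size factors, no low-count filter, the upper part of sites by mean signal, the authors' deposited adjusted p, leaving out each library, peaks with a −log10 q of at least 5 or a fold of at least 5, covered length in place of peak number, an overlap of at least 50% of the site, and a block by replicate number. Chosen after the data were seen were the comparisons of successive times, a spread from all 8 libraries of a table, DESeq2 with total-count size factors for successive times, stratified odds ratios by the site test or without a replicate, a 0 h library of its own for each time, a block by the letter of the count column, simulated lists of the observed lengths, and the correlation and TMM calls of ETOZnf against RUNX1.

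The reference used here is of another build than the files, so that the planned gene annotation, the 12 gene lists, the nearest genes of named sites and motif searches were not run. The planned pseudocounts for normalized values did not apply to counts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.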

Results

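CUT&RUN, in which an antibody directs a nuclease to cut out the DNA bound by a protein, was performed on 48 libraries from 3 human blood cancer lines. Kasumi-1 is an acute myeloid leukaemia line that carries the AML1-ETO (RUNX1-RUNX1T1) fusion, HEL is an erythroleukaemia line and OCI-LY1 is a B-cell lymphoma line. In each line both copies of SMARCA5, the ATPase of the ISWI chromatin remodellers, carried an FKBP12 degradation tag and a FLAG epitope, so that dTAG-47 at 500 nM directed the protein to degradation. FLAG was profiled in untreated cells and after 18 h. CTCF, a zinc-finger protein of insulators and loop anchors, was profiled at 0, 2, 6 and 24 h. In Kasumi-1, RUNX1 and the target of an in-house antibody labelled ETOZnf were profiled at 0 and 24 h, and the histone variant H2AZ and the Polycomb mark H3K27me3 were profiled in untreated cells. Each of the 24 groups held 2 biological replicates, and total counts over the tested sites ranged from 115525 to 7740568 per library. Sites are named by their hg19 positions; which genes they lie in or near was not analysed here.

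FLAG signal had fallen at nearly all SMARCA5 sites after 18 h of dTAG-47 in each line. In Kasumi-1, FLAG signal fell at 10494 of 10754 tested sites and rose at 25, with a median log2 change of -1.93. In HEL it fell at 12132 of 13460 sites and rose at 1 (median log2 -2.17), and in OCI-LY1 it fell at 8901 of 8995 sites and rose at 34 (median log2 -2.16; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The scaled count over all sites stood at 26.8% ± 5.35 of the untreated mean in Kasumi-1, 23.2% ± 12.6 in HEL and 23.4% ± 1.51 in OCI-LY1 (SD, n = 2 each). FLAG peaks per library numbered 17412 and 21917 in untreated Kasumi-1 against 1018 and 3373 at 18 h. They numbered 18822 and 22833 against 1293 and 1137 in HEL, and 13258 and 14174 against 311 and 519 in OCI-LY1. Over the 3 lines this was 5.46% of the untreated number (mean log2 ratio -4.20, lower in 6 of 6 treated libraries; exact permutation test within lines, two-sided, p = 0.00926, the smallest p that 12 libraries allow). Of the sites with a peak in both untreated libraries, a treated library kept 3.66% ± 0.432 in Kasumi-1, 5.37% ± 0.967 in HEL and 2.15% ± 0.737 in OCI-LY1 (SD, n = 2).

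The steepest FLAG falls lay at CTCF sites in OCI-LY1 and Kasumi-1 and away from them in HEL, while CTCF lay at 97.3%, 78.3% and 70.3% of all FLAG sites of these lines; the difference between lines was not tested. In HEL the first was at 12:76516312-76516712, where the scaled count fell from 102 ± 5.71 to 2.30 ± 0.544 (SD, n = 2; log2 -5.36, SE 0.909, edgeR adjusted p = 5.87e-06). None of the 10 steepest HEL falls lay at a CTCF site and 9 of them were at places with a FLAG site in no other line. In OCI-LY1 all 10 lay at CTCF sites, led by 4:102734605-102735005 (84.6 ± 7.28 to 2.93 ± 2.72, SD, n = 2; log2 -4.88, SE 0.416, edgeR adjusted p = 1.77e-29). In Kasumi-1 all 10 also lay at CTCF sites and 9 at H2AZ sites, led by 4:147866880-147867280 (71.2 ± 20.7 to 4.95 ± 0.394, SD, n = 2; log2 -3.80, SE 0.585, edgeR adjusted p = 9.71e-08). Across all HEL sites, the median log2 change was -2.55 without CTCF and -2.02 with it, and a lower call was rarer with CTCF within strata of the untreated count (Mantel-Haenszel odds ratio 0.135, 95% interval 0.109 to 0.167, adjusted p = 1.07e-94 over 89 tests of site groups; sites are not independent replicates). In OCI-LY1 the median was also lower without CTCF, at -2.29 (229 sites) against -2.16, although a lower call was more frequent with it (odds ratio 2.80, 95% interval 1.31 to 5.98, adjusted p = 0.0188), and in Kasumi-1 the medians were -1.79 without and -1.97 with CTCF (1.2496, 0.958 to 1.63, adjusted p = 0.133). A few FLAG sites rose. The CTCF sites are labelled BLfiltered (read as filtered against a blacklist of regions), and the FLAG sites are not. Whether the rises lie in such regions was not tested. The site at 2:133033246-133033646 went from 119 ± 10.6 to 392 ± 49.0 in Kasumi-1 (SD, n = 2; log2 1.72, SE 0.407, edgeR adjusted p = 7.25e-05), and the matching site at 2:133033248-133033648 from 265 ± 7.08 to 507 ± 63.1 in OCI-LY1 (log2 0.94, SE 0.132, edgeR adjusted p = 2.70e-12). Scaling on the typical site (TMM) moved the median log2 by 1.94 in Kasumi-1 and by 2.17 in HEL and in OCI-LY1, and split the calls 3 lower to 56 higher, 1591 to 1578 and 287 to 422. With that scaling 1 of the 10 Kasumi-1 falls and all 10 of the falls of the other lines remained called. Without HEL untreated library A or B (the libraries of a site table carry no replicate number) the HEL calls of edgeR were lost. The median log2 change in HEL was then -2.17 and -2.11, against -2.17 with all 4 libraries. Without HEL 18 h library A or B it was -2.84 and -1.67.

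**Figure D1:**
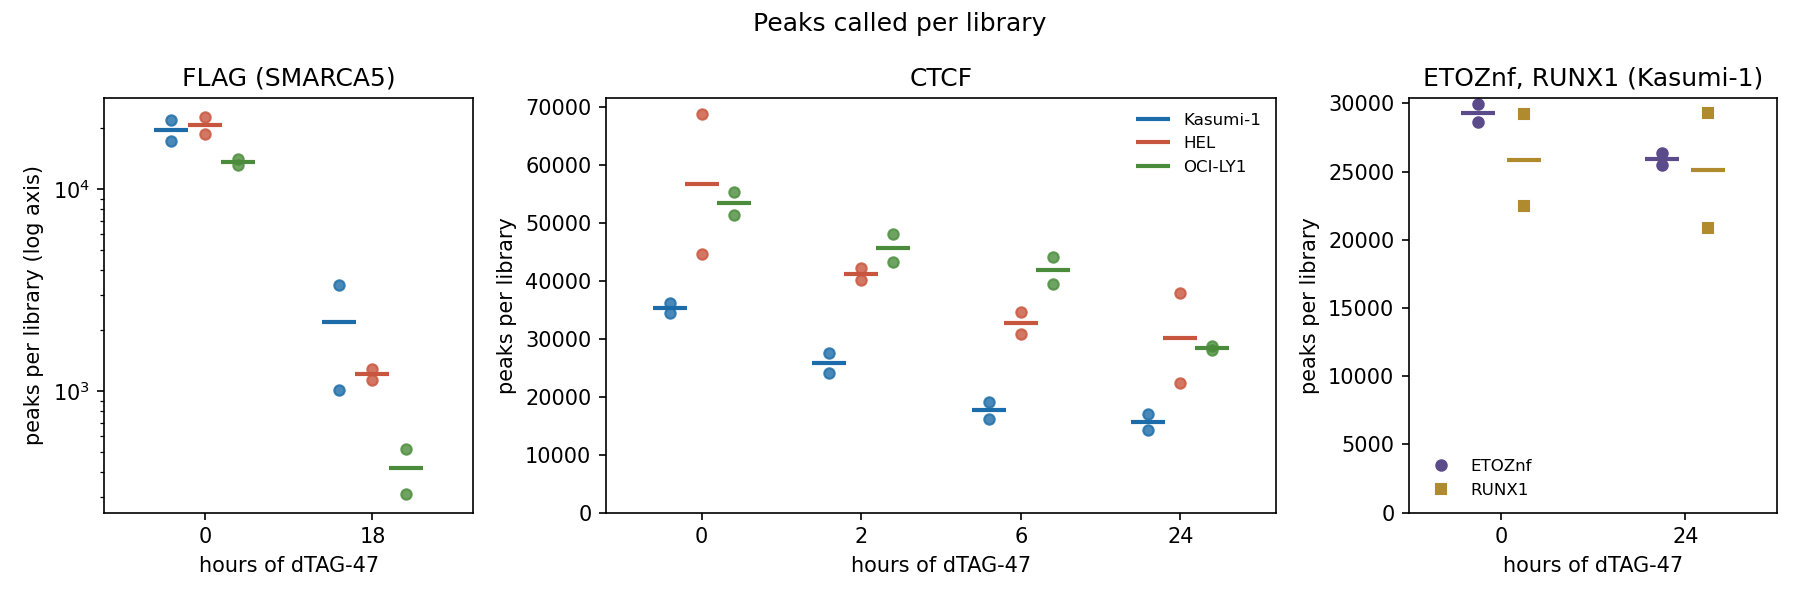
Peaks called per library (vertical axis, number of peaks; log axis for FLAG) against hours of dTAG-47 (horizontal axis), for FLAG and CTCF in 3 lines and for ETOZnf and RUNX1 in Kasumi-1. Points are libraries and bars are group means; FLAG libraries drop from between 13258 and 22833 peaks to between 311 and 3373.

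Before treatment SMARCA5 sites overlapped those of the other targets more often than shifted sites did. Circular shifts also move sites out of accessible DNA, so this excess cannot tell shared occupancy from shared accessibility. Of 10965 FLAG sites in Kasumi-1, 78.3% overlapped a CTCF site, 77.4% an H2AZ site, 83.3% an ETOZnf site and 79.0% a RUNX1 site. Circular shifts of the sites along the genome gave means of 1.46%, 1.12%, 1.20% and 1.10% (100 shifts each, highest 1.70%, 1.43%, 1.45% and 1.35%). H3K27me3 overlapped 40.9% of FLAG sites against 5.07% of shifted ones (highest 5.60%). All 5 marks met at 3233 FLAG sites (29.5%), and 456 (4.16%) had none of them. CTCF lay at 70.3% of 13741 FLAG sites in HEL and at 97.3% of 9309 in OCI-LY1 (shift means 1.95% and 2.71%). FLAG sites of Kasumi-1 were matched in both other lines at 28.5%, those of HEL at 22.6% and those of OCI-LY1 at 33.5%.

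CTCF signal declined across the genome after dTAG-47 was added. FLAG was not profiled at 2, 6 or 24 h, and no cells without the tag were profiled. The scaled count over all CTCF sites stood at 82.8% ± 13.3 of the 0 h mean after 2 h in Kasumi-1, 72.0% ± 14.5 in HEL and 80.6% ± 7.14 in OCI-LY1 (SD, n = 2). It stood at 57.0% ± 3.56, 58.2% ± 0.882 and 56.2% ± 2.80 after 6 h, and at 53.6% ± 7.20, 56.9% ± 3.24 and 45.8% ± 4.30 after 24 h. At 24 h the signal fell at 18029 of 29875 sites in Kasumi-1 and rose at 42, fell at 19557 of 39284 in HEL and rose at 75, and fell at 40047 of 46197 in OCI-LY1 and rose at 129 (edgeR, adjusted p under 0.05). The median log2 changes at 24 h were -0.93, -0.73 and -1.06. At 2 h the counts of lower and higher sites were 4253 and 50 in Kasumi-1, 550 and 2 in HEL, and 12831 and 209 in OCI-LY1. By the authors' adjusted p the lower sites at 2 h numbered 823, 1463 and 3846, and with the spread from all 8 libraries of a table there were 4449 in HEL. With a block by column letter, which leaves 1 residual degree of freedom, they numbered 7558, 14504 and 10917. At 6 h the counts of lower and higher sites were 18309 and 91, 19285 and 82, and 35761 and 144. From 2 to 6 h CTCF fell further at 5324, 585 and 19199 sites and rose at 1, 7 and 12, while from 6 to 24 h edgeR called 7, 1 and 47 sites lower and 0 higher in each line. DESeq2 with total-count scaling called 349, 3 and 8454 lower from 2 to 6 h. From 6 to 24 h 1742, 2357 and 7233 sites had an unadjusted p under 0.05, DESeq2 with total-count scaling called 0, 0 and 4 lower and 0 higher, and edgeR with TMM scaling called 1, 0 and 0 higher. With the spread from all 8 libraries edgeR called 5, 0 and 1159 lower, the last at a median log2 of -0.27 over all OCI-LY1 sites, and without one library 0 to 87 in OCI-LY1.

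CTCF peaks per library fell at each time. Over the 3 lines they stood at 77.4% of the 0 h number at 2 h (mean log2 ratio -0.37), 61.3% at 6 h (-0.71) and 49.8% at 24 h (-1.0). Each time was lower in 6 of 6 treated libraries (exact permutation tests within lines, two-sided, p = 0.00926 each, the smallest p possible, and 0.00926 after Benjamini-Hochberg adjustment over the 3 times). At 24 h the number was 44.2% in Kasumi-1, 52.6% in HEL and 53.2% in OCI-LY1. Of the sites called in both 0 h libraries, a 24 h library kept 48.1% ± 4.73 in Kasumi-1, 59.3% ± 13.6 in HEL and 54.9% ± 0.838 in OCI-LY1 (SD, n = 2). The HEL value combines 68.9% and 49.7%, from 37863 and 22449 peaks.

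The times share their 0 h libraries, and calls at 6 and 24 h overlapped at 15708 sites in Kasumi-1, 15914 in HEL and 34833 in OCI-LY1. Simulated unchanged groups against the same controls gave no lower calls, so that their overlap of 0 is no measure of the shared controls. Lists of the observed lengths from the lower end of the simulated tests shared 13398, 12677 and 32899 (5 simulations, highest 13457, 12712 and 32913), and independent lists of the same lengths would share 11062, 9602 and 30999. The log2 changes at 6 and 24 h correlated across sites at 0.86, 0.84 and 0.88, against 0.49, 0.47 and 0.50 in the simulation, with covariances of 0.603, 0.230 and 0.326 against 0.0425, 0.0427 and 0.0235. With a 0 h library of its own for each time, the covariances were 0.530 and 0.543 in Kasumi-1, 0.191 and 0.195 in HEL and 0.301 and 0.306 in OCI-LY1 for the 2 ways to assign the libraries, against 0.567, 0.225 and 0.32 from the same scaled counts with both 0 h libraries. Sites are not independent replicates, and part of the excess in shared calls may come from the shared controls. TMM scaling moved the median log2 at 2, 6 and 24 h by 0.32, 0.85 and 0.93 in Kasumi-1, by 0.45, 0.72 and 0.75 in HEL and by 0.32, 0.84 and 1.08 in OCI-LY1. Relative to that shift the calls at 24 h split into 6336 lower and 4956 higher, 4399 and 2900, and 9339 and 7476. At 2 h they split into 2829 and 2019, 523 and 163, and 4335 and 2880, and at 6 h into 5728 and 4983, 4679 and 3026, and 7616 and 5546. From 2 to 6 h the shifts were 0.55, 0.30 and 0.52 and the splits 398 to 98, 374 to 89 and 1686 to 578, and from 6 to 24 h OCI-LY1 shifted by 0.27.

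**Figure D2:**
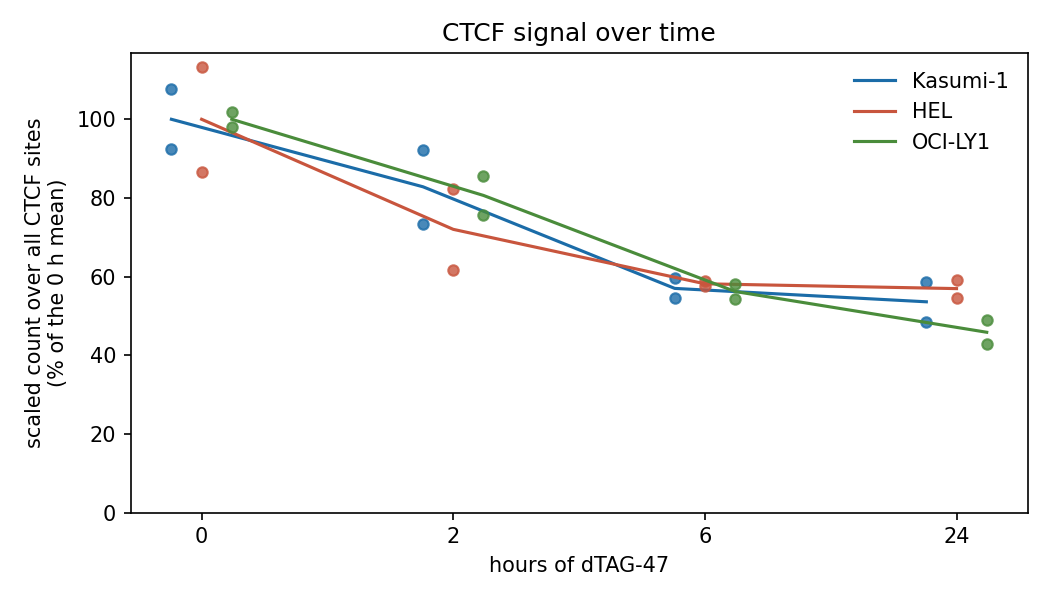
Scaled count summed over all CTCF sites as a percentage of the 0 h mean (vertical axis) at 0, 2, 6 and 24 h of dTAG-47 (horizontal axis, not to scale), in 3 lines. Points are libraries and lines join the group means, which reach 53.6% in Kasumi-1, 56.9% in HEL and 45.8% in OCI-LY1 at 24 h.

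Some counts of lower CTCF sites changed when 1 library was left out, which leaves 1 library in a group and fewer residual degrees of freedom. The edgeR calls of Kasumi-1 at 6 h were lost without either 0 h library. The median log2 change was then -0.745 (without A) and -1.003 (without B), against -0.867 with all 4 libraries. With all 4, DESeq2 with its own size factors called 1654 lower. In HEL the median was -0.721 or -0.698 without 6 h library A or B, against -0.697 with all 4 libraries. At 24 h it was -0.804 or -0.691 without 24 h library A or B, against -0.729. Without 0 h library A or B the HEL median was -0.507 or -0.849 at 6 h and -0.532 or -0.875 at 24 h. These medians therefore stayed negative whichever 1 library was left out, but their size depended on the 0 h library. The HEL counts without one library were 2376 or 2313 at 6 h (6 h library A or B left out), 2626 or 2488 at 24 h (24 h library A or B), and at 2 h 7 without 0 h library A, 142 without 2 h library A and 7 without 2 h library B. At 2 h the Kasumi-1 count was 938 or 2280 without a 0 h library and 1459 without 2 h library B, and the OCI-LY1 count was 5600 or 5199 without a 0 h library and 7759 without 2 h library B. The Kasumi-1 count at 24 h was 11559 without 0 h library A. From 2 to 6 h edgeR called 0 lower in Kasumi-1 without 2 h library A or B, with 5065 and 10156 sites at an unadjusted p under 0.05, and 421 or 126 without 6 h library A or B. In HEL it called 0 without 6 h library A or B, with 2071 and 1799 at an unadjusted p under 0.05, and 322 or 14005 without 2 h library A or B, and in OCI-LY1 5977 without 2 h library A and 10265 without 6 h library B.

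Individual CTCF sites lost almost all signal in more than 1 line. In Kasumi-1 the steepest fall was at 17:47512364-47512764, where the scaled count went from 125 ± 15.1 at 0 h to 33.4 ± 8.16 at 2 h, 11.5 ± 0.689 at 6 h and 3.48 ± 1.79 at 24 h (SD, n = 2). Its log2 changes were -1.91, -3.42 and -5.07 (24 h SE 0.425, edgeR adjusted p = 4.35e-29), and its 24 h changes in HEL and OCI-LY1 were -1.98 and -3.12. The log2 change was -4.76 at 12:53264227-53264627 and -4.62 at 10:65736409-65736809. A strong site on chromosome 19 lay among the 10 steepest falls of Kasumi-1 and of HEL. At 19:42210675-42211075 in Kasumi-1 the count went from 550 ± 71.9 to 27.8 ± 4.94 (SD, n = 2; log2 -4.29, SE 0.276, edgeR adjusted p = 5.78e-50), at the matching site in HEL from 1067 ± 206 to 142 ± 14.3 (log2 -2.91), and in OCI-LY1 the log2 change was -3.38. The site at 16:33618876-33619276 lay among the 10 steepest falls of HEL and OCI-LY1. There the count went from 1977 ± 73.8 to 132 ± 16.6 in OCI-LY1 (SD, n = 2; log2 -3.90, SE 0.185, edgeR adjusted p = 3.19e-94), and the log2 change was -2.84 in HEL and -3.18 in Kasumi-1. The HEL list was led by 8:143751062-143751462 (log2 -3.11, SE 0.368) and 14:75079235-75079635 (log2 -3.08, SE 0.352). The OCI-LY1 list was led by 12:126168247-126168647 (log2 -3.96, SE 0.286) and X:109411182-109411582 (log2 -3.93, SE 0.279).

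Of the 10 steepest falls per line, 10, 9 and 8 were at sites present in all 3 lines, and 2, 0 and 0 carried a SMARCA5 peak before treatment. Among all CTCF peak sites at 0 h, 71.8%, 55.4% and 45.4% were present in all 3 lines. Among lost and kept CTCF sites, 28.9%, 27.2% and 21.0% carried SMARCA5. Falls were named only at sites of at least median signal, and their counts were not tested against these shares. All 10 were already called lower at 6 h in each line, and 7, 3 and 10 at 2 h. With TMM scaling all 10 stayed called lower in each line, with log2 changes between -4.16 and -3.27 in Kasumi-1, -2.36 and -2.05 in HEL and -2.88 and -2.63 in OCI-LY1. A small number of CTCF sites gained signal. The largest gains at sites of at least median signal were at 22:29225489-29225889 in Kasumi-1 (41.9 ± 0.352 to 86.1 ± 3.53, SD, n = 2; log2 1.03, SE 0.288, edgeR adjusted p = 0.000974) and at 13:28033591-28033991 in OCI-LY1 (137 ± 11.1 to 252 ± 37.6; log2 0.88, SE 0.176, edgeR adjusted p = 1.15e-06). The second of these carried a SMARCA5 peak before treatment. The Kasumi-1 gain was not shared, since the same place changed by a log2 of -0.66 in OCI-LY1 (edgeR adjusted p under 0.05) and -0.16 in HEL (edgeR adjusted p = 0.674). In HEL none of the 75 gains had median signal or more.

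Lost CTCF sites coincided between the lines. Among 20421 places with a CTCF site in all 3 lines at 0 h, 32.3% were lost in Kasumi-1, 16.8% in HEL and 17.4% in OCI-LY1, where lost means a peak in neither 24 h library. At 1259 places the site was lost in all 3 lines, against 193 from the product of the rates and at most 227 in 200 permutations of the sites. Within strata of 0 h peak strength the expectation was 385 and the highest permutation 429. Sites found in 1 line were lost at 66.0% in Kasumi-1, 44.3% in HEL and 56.8% in OCI-LY1, and sites found in all 3 lines at 32.5%, 17.1% and 17.4%. By counts 47.6%, 19.7% and 73.3% of sites found in 1 line were called lower, against 62.4%, 66.0% and 97.0% of sites found in all 3. Within strata of the 0 h count the odds ratio of a lower call was 0.759, 0.254 and 0.409 for sites found in 1 line, and 0.955 (95% interval 0.902 to 1.01), 2.43 and 2.81 for sites found in all 3, each against all other sites. Of 20029 places tested in all lines, 9997 were called lower in each, against 8342 from the product of the rates.

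CTCF sites that carried SMARCA5 before treatment kept their peaks more often. A SMARCA5 peak lay at 19.2% of lost against 39.7% of kept CTCF sites in Kasumi-1, where kept means a peak in both 24 h libraries (odds ratio 0.361, 95% interval 0.340 to 0.383). In HEL it lay at 10.6% against 37.2% (0.201, 0.187 to 0.215) and in OCI-LY1 at 3.6% against 34.8% (0.0700, 0.0641 to 0.0764; Fisher's exact test over sites, p = 9.56e-254 in Kasumi-1 and below 1e-300 in the other lines, not independent replicates). Within strata of 0 h peak strength the Mantel-Haenszel odds ratios were 0.418, 0.146 and 0.0847. Without replicate 1 or 2 of each group, with sites, loss and keeping read from 1 library, the unstratified odds ratios were 0.446 and 0.387 in Kasumi-1, 0.279 and 0.231 in HEL, and 0.153 and 0.140 in OCI-LY1. The stratified ones were 0.509 and 0.487, 0.261 and 0.278, and 0.201 and 0.159. In the strongest stratum 8.36% of sites with SMARCA5 and 26.1% of sites without it were lost in Kasumi-1, 0.334% and 4.18% in HEL, and 0.842% and 11.2% in OCI-LY1. In the weakest stratum the shares were 74.2% and 81.8%, 57.6% and 85.2%, and 38.2% and 84.3%. By counts the contrast was small: the median log2 change of sites with SMARCA5 was -0.80 against -1.01 in Kasumi-1, -0.67 against -0.76 in HEL and -1.01 against -1.08 in OCI-LY1, so both kinds of site declined. With TMM scaling sites with SMARCA5 had medians of 0.12, 0.08 and 0.07, against -0.08, -0.01 and -0.0025. By counts 91.9% of OCI-LY1 sites with SMARCA5 and 85.5% of the others were called lower. With loss read as a lower call against no call, which leaves out the sites called higher, the odds ratio turned to 1.95 in OCI-LY1, and within strata of the 0 h count it was 0.684.

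**Figure D3:**
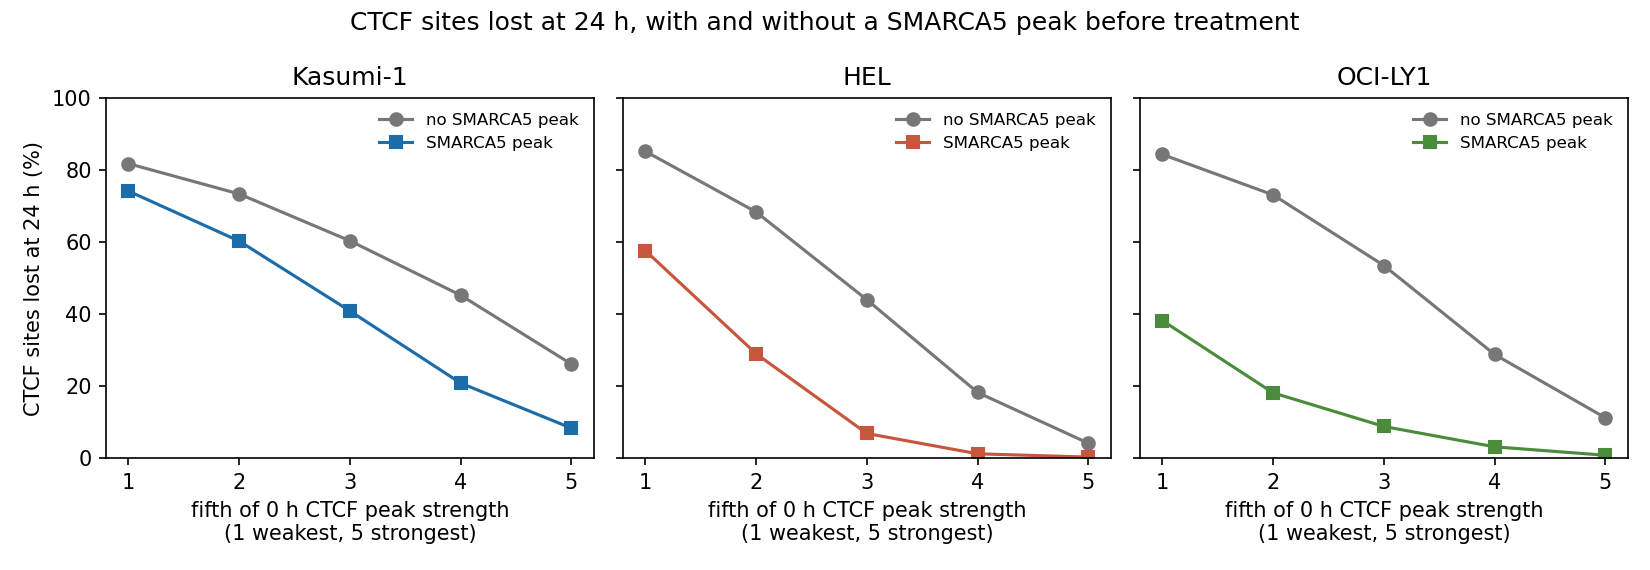
CTCF sites lost at 24 h (vertical axis, percent of lost and kept sites) by stratum of 0 h CTCF peak strength (horizontal axis, 1 weakest, 5 strongest), for sites with a SMARCA5 peak before treatment (squares) and without (circles) in each line. In each stratum the sites with SMARCA5 lie lower, at 8.36%, 0.334% and 0.842% against 26.1%, 4.18% and 11.2% in the strongest stratum of Kasumi-1, HEL and OCI-LY1.

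In Kasumi-1, CTCF sites with H2AZ were also kept more often. H2AZ lay at 32.2% of lost and 53.8% of kept sites (odds ratio 0.408, 95% interval 0.387 to 0.431; Mantel-Haenszel 0.410). In the weakest stratum 79.4% of sites with H2AZ and 81.0% of the others were lost (Fisher's exact test over sites, p = 0.178), and in the strongest stratum 6.90% and 32.6%. H3K27me3 lay at 28.8% of lost and 41.9% of kept sites (0.561, Mantel-Haenszel 0.743). By counts it pointed the other way: 69.1% of CTCF sites with H3K27me3 and 56.2% of the others were called lower at 24 h. The odds ratio of a lower call against no call, which leaves out the sites called higher, was 1.74, and 1.56 within strata of the 0 h count.

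ETOZnf signal fell in Kasumi-1 after 24 h, most at sites that also held CTCF or H2AZ. It fell at 12985 of 25067 sites and rose at 777 (edgeR, adjusted p under 0.05; median log2 -0.57), and the scaled total stood at 66.2% ± 2.46 of the 0 h mean (SD, n = 2). The median log2 change was -0.77 at sites with CTCF and -0.32 at sites without, -0.76 with H2AZ and -0.27 without, and -0.72 with SMARCA5 and -0.46 without. A lower call was more frequent with each within strata of the 0 h count: Mantel-Haenszel odds ratios 3.6 for CTCF (95% interval 3.39 to 3.82), 3.89 for H2AZ (3.66 to 4.14) and 1.69 for SMARCA5 (1.59 to 1.80; adjusted p = 2.14e-60 or smaller over 89 tests of site groups). The steepest fall was at 19:3275995-3276395, from 243 ± 12.3 to 11.1 ± 0.515 (SD, n = 2; log2 -4.43, SE 0.224, edgeR adjusted p = 1.39e-82), near the CTCF fall at 19:3275455-3275855 (log2 -4.27). The next falls were at 19:6516204-6516604 (log2 -4.33) and 19:46282555-46282955 (log2 -4.32). All of the 10 steepest falls lay at CTCF, H2AZ and RUNX1 sites and 9 at SMARCA5 sites. One of them, at 1:11538847-11539247 (log2 -3.36), overlaps a steep CTCF fall of HEL at 1:11538830-11539230 (log2 -2.92), where CTCF in Kasumi-1 changed by -3.12. The largest rises, at 12:123543885-123544285 (18.9 ± 6.45 to 67.2 ± 10.1, SD, n = 2; log2 1.85, SE 0.283, edgeR adjusted p = 1.06e-09) and 17:75387977-75388377 (log2 1.84), carried none of CTCF, H2AZ and SMARCA5. TMM scaling moved the median by 0.57 and split the calls into 3653 lower and 3665 higher. Relative to that shift sites with CTCF, H2AZ or SMARCA5 stayed lower (medians -0.20, -0.18 and -0.15) and sites without them turned higher (0.26, 0.31 and 0.11). ETOZnf peaks numbered 28607 and 29947 at 0 h and 25473 and 26388 at 24 h (88.6%; exact permutation test, two-sided, p = 0.33, the smallest p that 2 libraries against 2 allow).

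RUNX1 showed no site past the threshold at 24 h, and its replicates moved apart. The scaled total of the 24 h libraries stood at 74.4% and 165% of the 0 h mean (119.8% ± 64.3, SD, n = 2). edgeR called 0 of 22013 sites, with 617 at an unadjusted p under 0.05, while DESeq2 with its own size factors called 308 lower and 69 higher and edgeR with TMM 2263 lower and 1984 higher. Without 24 h library A, 309 sites were lower and 14113 higher, and without library B 5851 were lower and 393 higher. The median log2 change of library A was -0.52 at sites with CTCF and -0.21 at sites without, and that of library B was 0.63 and 0.92. RUNX1 peaks numbered 22485 and 29233 at 0 h and 20887 and 29305 at 24 h (96.5%, mean log2 ratio -0.05; exact permutation test, two-sided, p = 1). Of 23121 ETOZnf sites at 0 h, 17619 (76.2%) overlapped a RUNX1 site against 1.23% of shifted sites, and 89.2% of 19653 RUNX1 sites overlapped an ETOZnf site. As edgeR called 0 RUNX1 sites, ETOZnf calls could not be set against RUNX1 calls as planned. The 24 h changes of the 2 targets correlated at 18602 shared sites, with a median Spearman rho within strata of ETOZnf signal of 0.724. It was 0.666 and 0.688 with RUNX1 library A or B alone. Whether both antibodies detect the AML1-ETO (RUNX1-RUNX1T1) fusion that Kasumi-1 carries was not tested, so the 2 targets may not be separate proteins. With TMM scaling ETOZnf was lower at 70.3% of 2008 shared sites where RUNX1 was lower and at 9.33% of the others.

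**Figure D4:**
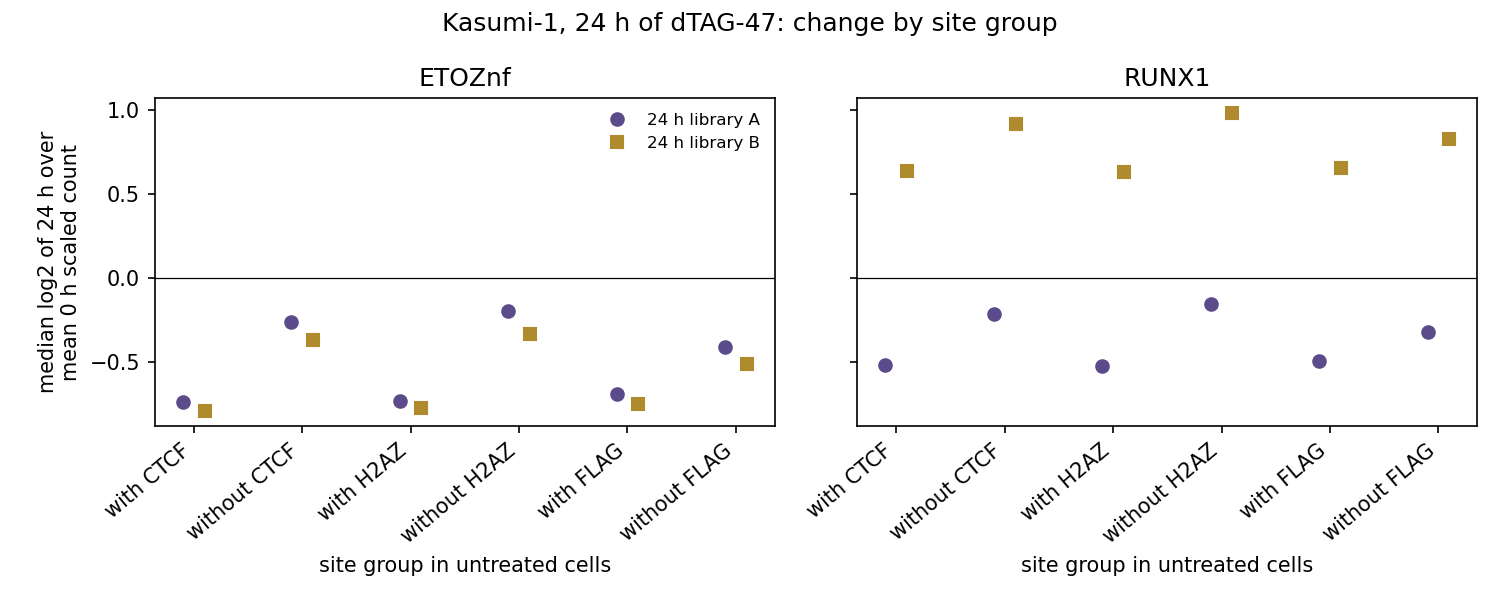
Median log2 ratio of each 24 h library's scaled count to the mean 0 h scaled count (vertical axis) for ETOZnf and RUNX1 sites of Kasumi-1, by whether the site carried CTCF, H2AZ or SMARCA5 (FLAG) in untreated cells (horizontal axis). Each point is 1 library; sites with CTCF lie lower than sites without it in each library, and RUNX1 library A (-0.52 and -0.21) lies below 0 where library B (0.63 and 0.92) lies above it.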

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

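Tests chosen only after their result was seen in this part are the peak-number test of the total-count scaling, the test of a single factor per library, whose wording was changed after the results were seen, the stratified odds ratios without a replicate and the split of SMARCA5 sites by H2AZ.

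By peak calls, the association of CTCF loss at 24 h with SMARCA5 differed between the lines. The stratified odds ratio of a SMARCA5 peak at lost against kept CTCF sites was 0.418 in Kasumi-1, 0.146 in HEL and 0.0847 in OCI-LY1. The ratios between lines were 2.86 (Kasumi-1 over HEL), 4.94 (Kasumi-1 over OCI-LY1) and 1.73 (HEL over OCI-LY1), with a z of at least 8.15 for the difference of log odds ratios over sites, which are not independent replicates. Without replicate 1 of each group they were 1.95, 2.54 and 1.30, and without replicate 2 they were 1.75, 3.06 and 1.74, from odds ratios of 0.509 and 0.487 in Kasumi-1, 0.261 and 0.278 in HEL and 0.201 and 0.159 in OCI-LY1. By counts this order was not seen: within strata of the 0 h count the odds ratio of a lower call with SMARCA5 was 0.720 in Kasumi-1, 0.472 in HEL and 0.675 in OCI-LY1, and the log2 change with minus without SMARCA5 was 0.205, 0.166 and 0.206 (mean over strata). The lines also differ in peak numbers and in the share of lost and kept CTCF sites that carry SMARCA5 (28.9%, 27.2% and 21.0%).

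The first pattern weighed is the nearly one-sided fall of CTCF at 24 h in each line. Total-count scaling as the source of the shared fall cannot be decided by the peak lists. They are called within each library, so that their fall did not rest on that scaling. They held 49.8% of the 0 h number at 24 h, with each 24 h library below each 0 h library of its line. Yet a smaller share of reads at the sites would lower both the scaled counts and the number of peaks. Depth was not matched either: size factors at 0 and 24 h were 1.68 and 0.938 against 1.05 and 0.698 in HEL. They were 0.840 and 1.23 against 0.903 and 1.05 in Kasumi-1, and 0.963 and 1.16 against 1.02 and 0.873 in OCI-LY1. A single factor per library would let sites of similar strength fall alike apart from noise, yet within strata of 0 h signal their falls correlated between lines, with a median Spearman rho of 0.546 in the lowest pair of lines. More background in the 24 h libraries on top of an even fall would make weak sites fall less: the weakest stratum minus the strongest gave 0.39 and 0.633 in HEL and 0.50 and 0.37 in OCI-LY1, but -0.05 and -0.09 in Kasumi-1 (one value per 0 h library used for the strata), so whether background adds to the fall cannot be told apart over all lines, as the lines disagree. That correlation argues against a single factor on all counts of a library as the whole of the fall. It cannot exclude an even loss above a background that differs between sites alike in each line. Background per site was not measured. A technical loss of enrichment with time and a loss of CTCF binding, the biological reading that the design gives, both stay open. The sources used here do not tell whether the authors' size factors include a spike-in, and each group had 2 libraries.

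The second pattern is the rarity of SMARCA5 at lost CTCF sites. That weak sites drop below the peak threshold and seldom carry SMARCA5 is argued against, as the whole of the pattern, by the stratified odds ratio nearest to 1. It was 0.418 (95% interval 0.391 to 0.448, Kasumi-1). Strength within a stratum and the width of the sites were not matched, so a part by this route stays open. Loss of a peak call without a different fall in counts is argued against by the counts, in which sites with SMARCA5 fell less, by a mean over strata of 0.166 on the log2 scale in HEL, 0.20 in Kasumi-1 and 0.21 in OCI-LY1 (lowest stratum 0.0892, 0.126 and 0.183). Whether any accessible site is kept, with or without SMARCA5, cannot be decided here, with H2AZ as the sign of accessibility. By peak calls, sites with H2AZ and no SMARCA5 had a stratified odds ratio of loss of 0.505 (0.466 to 0.548) against sites with neither. That of sites with SMARCA5 was lower (0.357, 0.33 to 0.383), but 5581 of these 6517 sites also carried H2AZ (sites with both 0.323, 0.30 to 0.348). The 936 sites with SMARCA5 and no H2AZ stood at 0.595 (0.514 to 0.689), no lower than H2AZ alone. H2AZ was read as present or absent, without its strength. By counts this explanation also stays open, as does loss of a call without a different fall at H2AZ sites. Kasumi-1 CTCF sites with H2AZ had a median log2 change at 24 h of -0.816 with SMARCA5 and -0.820 without it (57.2% and 54.5% called lower). SMARCA5 itself, as the biological reading, stays open as untested, and accessibility was not measured.

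The third pattern is that 40.9% of SMARCA5 sites of untreated Kasumi-1 overlap an H3K27me3 site, a mark of repressed chromatin. A candidate explanation is that nuclease cuts of the H3K27me3 libraries at accessible sites were called as peaks: the 4436 H3K27me3 sites with SMARCA5 were narrower than the 48163 others (median 939 against 1725 bp, ratio 0.544), as this predicts. Their median fold enrichment was higher (2.68 against 2.02, the authors' value), which this test does not address. Mixed cell states and real co-occupancy were not tested.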

How the results depend on the processing

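Chosen after the data were seen were the comparisons of successive times with all their alternatives, the spread from all 8 libraries, DESeq2 with total-count size factors, the stratified odds ratios by the site test or without a replicate, a 0 h library of its own for each time, a block by column letter, simulated lists of the observed lengths and the correlation of ETOZnf with RUNX1; the other alternatives were planned. Lines are given in the order Kasumi-1, HEL, OCI-LY1 and times in the order 2, 6, 24 h. Of the counts of lower sites 122 stayed within 1.5 times the count given in the report, 127 did not and 6 turned to a majority of higher calls. Of the log2 ratios of peak numbers 78 kept direction and side of the threshold and 2 reversed, and of the odds ratios 42 did and 3 reversed. All 23 folds over an expectation kept their side, those of SMARCA5 overlap over shifted sites and those of CTCF loss shared between lines. Where a value changed, the cause was not tested, unless a fit with fewer libraries or fewer sites explains it by construction.

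TMM scaling and DESeq2's own size factors centre the changes on the typical site, so that a fall shared by most sites leaves the calls by construction. With TMM scaling FLAG had 3, 1591 and 287 lower sites, and higher calls outnumbered lower ones in Kasumi-1 and OCI-LY1. For CTCF there were 2829 (Kasumi-1) and 4335 (OCI-LY1) lower sites at 2 h, 5728, 4679 and 7616 at 6 h, and 6336, 4399 and 9339 at 24 h. ETOZnf had 3653, just below its 3665 higher calls, and RUNX1 2263. The 6 against 2 h counts were 398, 374 and 1686, and those of 24 against 6 h 3 in HEL and 1 in OCI-LY1. DESeq2 with its size factors gave 0, 233 and 24 lower FLAG sites, with more higher calls in each line. It gave 232, 102 and 943 lower CTCF sites at 2 h, 1654, 1291 and 4107 at 6 h, 2174, 1249 and 4854 at 24 h, 775 for ETOZnf and 308 for RUNX1. For 6 against 2 h it gave 1, 5 and 298, and for 24 against 6 h 0 in each line. DESeq2 with total-count size factors gave 349, 3 and 8454 for 6 against 2 h and 0, 0 and 4 for 24 against 6 h.

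With an adjusted p under 0.01, CTCF at 2 h had 2351, 121 and 7833 lower sites, HEL had 12463 at 6 h and 12197 at 24 h, 6 against 2 h had 2048, 102 and 11018, and 24 against 6 h had 3 in Kasumi-1 and 4 in OCI-LY1. With a fold of at least 2, OCI-LY1 CTCF had 2576, 16739 and 25328, HEL 10708 at 6 h and 11439 at 24 h, ETOZnf 5686, and OCI-LY1 6 against 2 h 4864. By the authors' deposited adjusted p, CTCF at 2 h had 823, 1463 and 3846, Kasumi-1 at 6 h 11686, ETOZnf 7275 and RUNX1 5. Without the low-count filter 24 against 6 h in Kasumi-1 had 3. With the spread from all 8 libraries HEL at 2 h had 4449, and 24 against 6 h had 0 in HEL and 1159 in OCI-LY1. Among the upper part of sites by mean signal, which holds fewer sites by construction, FLAG had 5324, 6247 and 4487 lower sites, CTCF 1418, 4 and 7593 at 2 h, 9109, 12423 and 19959 at 6 h, and 8886, 12451 and 22251 at 24 h, ETOZnf 8547, and 6 against 2 h 2941 in Kasumi-1 and 116 in HEL.

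Leaving out each library in turn leaves 1 arm of a site test with a single library, assumed to vary like the others, and fewer residual degrees of freedom. The ranges of lower sites were 0 to 13415 for FLAG in HEL. For CTCF at 2 h they were 938 to 5758, 7 to 657 and 5199 to 15216. At 6 h they were 0 to 15160 in Kasumi-1 and 2313 to 28495 in HEL, and at 24 h 11559 to 17682 in Kasumi-1 and 2488 to 27761 in HEL. RUNX1 ranged from 0 to 5851. For 6 against 2 h the ranges were 0 to 421 (0 without either 2 h library, with 5065 and 10156 sites at an unadjusted p under 0.05, and 421 or 126 without 6 h library A or B), 0 to 14005 (0 without either 6 h library, with 2071 and 1799 at an unadjusted p under 0.05, 322 and 14005 without 2 h library A or B) and 5977 to 16947 (5977 without 2 h library A, 10265 without 6 h library B). For 24 against 6 h they were 0 to 0, 0 to 8 (8 without 24 h library A, 0 without 6 h library A) and 0 to 87 (0 or 27 without 24 h library A or B, 1 or 87 without 6 h library A or B), with 794 to 3010 sites at an unadjusted p under 0.05 where edgeR gave 0. The log2 ratio of RUNX1 peak numbers ranged from -0.30 to 0.19 and reversed without 0 h replicate 2 (0.14) or 24 h replicate 1 (0.19).

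The share of sites kept was lower where an overlap of at least 50% of the site was asked: 1.43%, 2.24% and 1.3% for FLAG, and for CTCF 63.4%, 65.7% and 71.8% at 2 h, 42.8%, 45.9% and 59.5% at 6 h, and 35.9%, 43.4% and 37.9% at 24 h. With peaks of a −log10 q of at least 5 it was 2.94% for FLAG in Kasumi-1, and 71.4% and 51.6% for CTCF in OCI-LY1 at 6 and 24 h. Without 1 untreated or 1 treated library, the shares ranged from 2.24% to 3.97% and from 3.67% to 6.05% for FLAG in Kasumi-1 and HEL. For CTCF they ranged from 63.9% to 78.1%, 49.8% to 82.4% and 72.1% to 86.1% at 2 h, 45.6% to 57.8%, 39.0% to 66.5% and 62.9% to 73.6% at 6 h, and 40.2% to 51.5%, 36.1% to 68.9% and 45.9% to 55.5% at 24 h, the low ends without a 0 h replicate, where peaks found in 1 replicate only enter as sites by construction. The overlap of ETOZnf with RUNX1 was 75.2% where at least 50% of the ETOZnf site was asked. Without replicate 1 or 2 the odds ratios of SMARCA5 at lost sites lay nearer to 1, from 0.387 to 0.509, 0.231 to 0.279 and 0.140 to 0.201 with and without strata. The odds ratios that reversed were those by the site test, 1.95 for SMARCA5 in OCI-LY1 (below 1 within strata of the 0 h count), and 1.74 and, within strata, 1.56 for H3K27me3.

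Replicate numbers pair libraries by number only, and same-numbered libraries deviated from their group means in the same direction in some comparisons and lines and not in others. With the replicate block the log2 ratios of peak numbers were the same by construction (-4.20 for FLAG, -0.37, -0.71 and -1.0 for CTCF, -0.17 for ETOZnf, -0.05 for RUNX1), and the exact sign-flip test gave p = 0.0312 for FLAG and CTCF, the smallest it allows, 0.5 for ETOZnf and 1 for RUNX1, so that no call changed. The count columns of the site tests carry no replicate number, but share the letters A and B, and the labels do not say that a letter marks a shared batch. The differences between column A and column B correlated across sites between the 2 groups compared at -0.193 to 0.186, with the highest value for HEL CTCF at 0 and 2 h. With a replicate block by column letter, which leaves 1 residual degree of freedom, lower sites numbered 5625 for FLAG in HEL, 7558 and 14504 for CTCF at 2 h in Kasumi-1 and HEL, 8153 for 6 against 2 h in Kasumi-1, and 3, 3 and 24 for 24 against 6 h, and the other 13 counts stayed within 1.5 times. Counts over the sites were lowest in FLAG libraries at 18 h (115525 to 321301), but depth alone does not set the limit: in simulated data changed sites at log2 -2 were recovered at 100% in OCI-LY1, with the lowest counts, and at 28% in HEL. For RUNX1 it was 6%.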

Other observations

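The test of ETOZnf against CTCF in this part was chosen only after its result was seen; the tests of RUNX1 against CTCF and of neighbouring sites were not.

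CTCF sites on chromosome X were called lower more often than other sites of similar signal in HEL and OCI-LY1 at 6 and 24 h, and less often in Kasumi-1 at 2 and 6 h. At 24 h 63.7% of 509 sites on chromosome X were called lower in HEL and 93.4% of 1019 in OCI-LY1, against 49.8% and 86.7% of all sites (Mantel-Haenszel odds ratios within strata of the 0 h count 2.82, 95% interval 2.33 to 3.40, and 3.65, 2.83 to 4.71). In Kasumi-1 51.4% of 622 sites were called lower against 60.3% of all (0.885, 0.753 to 1.04). At 2 h the stratified odds ratios were 0.706 (0.544 to 0.917) in Kasumi-1, 1.71 (1.01 to 2.87, adjusted p = 0.0775 over 89 Mantel-Haenszel chi-square tests) in HEL and 1.02 (0.882 to 1.18) in OCI-LY1, and at 6 h 0.781 (0.665 to 0.918), 2.63 (2.19 to 3.15) and 1.56 (1.34 to 1.83). The median log2 change at these sites was -0.88 in HEL, -1.18 in OCI-LY1 and -0.88 in Kasumi-1, and with TMM scaling it was -0.13, -0.10 and 0.04. The difference between the lines was not tested. No other chromosome was examined in this way, so whether chromosome X departs more than others is not known.

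CTCF sites of Kasumi-1 that shared a place with ETOZnf or RUNX1 fell less at 24 h than other CTCF sites. The median log2 change at 24 h was -0.78 at 13186 sites with ETOZnf against -1.14 at sites without it, and -0.77 at 12063 sites with RUNX1 against -1.11 (stratified odds ratios of a lower call 0.558 and 0.556). With TMM scaling the medians were 0.15 against -0.21, and 0.16 against -0.19. At the same time ETOZnf fell more at its sites with CTCF, as given above.

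One hypothesis is that the losses of ETOZnf and CTCF go together place by place. At 11318 shared sites the 24 h changes of ETOZnf and CTCF correlated with a median Spearman rho of 0.477 within strata of ETOZnf signal (0.455 to 0.498 over the strata), and each 24 h library alone gave 0.45 and 0.44. Where CTCF was called lower the median ETOZnf change was -0.97, and at the other shared sites -0.58. RUNX1 gave the same order at 10384 shared sites although its libraries moved apart as a whole: rho was 0.428 with library A alone and 0.44 with library B alone. The correlations are across sites, which are not independent, and a shared change in accessibility, signal of one protein read at the site of the other, and a direct dependence may each give them.

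Another hypothesis is that CTCF loss may be grouped along the chromosome. Given that the nearest neighbouring CTCF site within 10 kb was called lower at 24 h, a site was more often lower itself, with an odds ratio within strata of 0 h signal of at least 2.05 (HEL, 95% interval 1.91 to 2.19; 2.40 in Kasumi-1 and 2.52 in OCI-LY1). Within strata of both sites' signal the odds ratios were 2.40, 2.27 and 3.11. Pairs of close sites can share fragments and chromatin state, which was not separated here.

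CTCF gains at 24 h in HEL lay at weak sites: the 75 gains had a median mean signal of 25.3 scaled counts against 52.6 over all sites. In OCI-LY1 the 129 gains had 34.5 against 64.5, and in Kasumi-1 the 42 gains had 44.4 against 31.1. ETOZnf gains had 24.2 against 40.8.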
